A study of Homo sapiens with 6 samples.

How the data were processed

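Gene expression was measured in p53 knock-down HCT116 cells on 6 Agilent 2-colour arrays, 3 after a single 2 Gy dose and 3 after 5 fractions of 2 Gy. Per the labels' protocols, total RNA was amplified from 1 ug, and cRNA of non-irradiated cells was labelled with Cy3 and of irradiated cells with Cy5, on every array. Arrays were grouped by the treatment in the labels, and the labels call the replicates biological. The titles of the fractionated group write the fractions and the dose in the other order than the remaining labels, and 5 fractions of 2 Gy was used.

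The scanner files were made with ImaGene 9.0, per the file headers, as a mean, median and mode intensity of each spot in each channel, with no background correction, logarithm or normalization. The deposited intensity files hold 45220 spots per array, of which 43118 are probe spots, 153 negative controls and 1224 positive controls, and 725 empty positions were left out. The deposited series table holds log2 ratios of Cy5 over Cy3, whose method is not given in the sources used here. Set against the scanner values, that table had a slope of 0.998 to 1 with the raw log2 ratio, which settles its scale and direction, and it lacked the raw ratio's trend with intensity. The column medians were -0.00325, -0.00132 and -0.00419 for the single-dose arrays and -0.00304, -0.00776 and -0.00904 for the fractionated arrays, and how it was centred is not known. It was used only as an alternative, and its correlation across probes with the values computed here was 0.989 to 0.993.

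Spot means were corrected with limma 3.58.1 in R 4.3.3 (backgroundCorrect, normexp, offset 50), normalized by loess within each array with control spots at weight 0, and averaged over the spots of a probe. The design had assumed a local background, but the files hold none, so normexp was run on the foreground alone. A probe was well above background in a channel when the mean of its spots exceeded the median of the negative controls by 2.6 times their robust SD. A probe was kept if it was well above background in either channel on at least 3 arrays, which left 20951 of 34127 distinct probes, and 16513 genes after the brightest probe of each gene was taken. Spots of flag 2 were dropped. Flag 3, whose meaning the files do not define, was kept. It marked 0.146% of spots at a mean log2 intensity under 10 and 84.4% of those over 15. Where flag 3 was left out, probes without a value on every array were dropped, bright ones most. Medians in that setting can therefore rest on fewer members or on other probes. Saturation was set at a spot median of 65000.

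Probes were named through the accessions of a RefSeq gene table of the assembly GRCh38.p14, which gave 25771 names, through current symbols (2207) or synonyms (499), and otherwise by the name in the file (1356). No name was given to 4294 probes. The files name no genome build, so no coordinates are given. A gene not well above background, or saturated, on all arrays of a group in a channel has only a bound there, given as at least N-fold from per-channel values after loess and Aquantile, and open to dye bias. Whether a spot of a multigene family reads its copies was not resolved.

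All 6 arrays entered 1 limma model (lmFit and eBayes) with a mean per group, 4 residual and 11.9 moderated degrees of freedom. Each group's mean was tested against 0 and the difference of the means was tested, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from this model. Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 of 26 lists with at least 5 tested members, and again with an estimated correlation and with fry. With an estimated correlation none of the list calls held. Before the data were examined, the sample groups, the model, the lists, the alternatives and the rule for named genes were fixed. The rule takes, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among genes with a symbol, with the same sign on all 3 arrays where compared with control. It adds up to 4 members of each list with the smallest p, and a set of genes named in advance. Genes chosen later are said to be so, and some genes that the rule names are not reported here.

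The alternatives were another background correction, offset 10, median centring in place of loess, Aquantile, other filters on dim probes, the mean of all probes of a gene, the deposited table, array weights, each group's own arrays, the replicate number and the slide as blocks, and leaving out each array. Leaving out flag 3, spot medians, normexp on the negative controls, slide as a fixed term and the arrays of slide 1 alone were added after the data were seen. Agilent's own processed signals are not columns of the files used here, and that alternative was not run. Slide and position were read from the scanner headers as slide 1 and 2.

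The procedure was tested on simulated data of the 16513 genes. Of genes changed by 0.5, 1 and 2 on the log2 scale, 48.8%, 91.1% and 100% were called in the single-dose comparison, 36.6%, 98.5% and 100% in the fractionated one and 17.9%, 79.5% and 100% between the schedules. False calls made up 2.53%, 3.31% and 4.74% of calls in these comparisons. The simulated arrays held no dye effect of single probes, no slide effect and noise independent between genes. Far fewer genes changed in them than were called in the real data, so these shares do not cover such effects. The median estimate for a change of 1 was 0.787, 0.836 and 0.787, and 0.935, 0.978 and 0.954 for bright genes, so that folds of dim genes are understated.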

Results

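HCT116 is an established human colorectal cancer cell line. In these cells p53, the transcription factor that controls much of the response to DNA damage, was knocked down with a short hairpin RNA, which per the labels left expression reduced by 85 to 90%. The knock-down cells received X-rays either as a single 2 Gy dose or as 5 fractions of 2 Gy, and RNA was taken 4 h later. Each of 6 2-colour arrays carried RNA of irradiated cells in Cy5 and RNA of non-irradiated knock-down cells in Cy3, so that an array's ratio compares irradiated with control cells. There were 3 arrays per schedule, described in the labels as biological replicates, and 3 arrays limit the precision of each mean. The median Cy3 spot intensity ranged from 509.72 to 583.29 over the 6 arrays. The median Cy5 intensity was 490.81, 371.73 and 353.82 on the single-dose arrays and 376.96, 806.95 and 536.21 on the fractionated arrays. Between 56.6% and 61.9% of distinct probes were well above background in Cy3, and between 48.6% and 58.5% in Cy5. After filtering, 16513 genes were tested.

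Each log2 ratio is the mean over 3 arrays of irradiated over control. The standard error (SE) given with it is the model's moderated one, pooled over both schedules. It is thus not the spread of that schedule's 3 arrays alone. Both channels held knock-down cells, so no ratio checks the knock-down itself. The labels do not say when the control cells of the fractionated schedule were harvested, so a difference in time in culture is not separated from the doses in its ratios or in the comparison of the schedules. Because the dyes were not swapped, a dye effect of a single probe stays in every ratio to control and cancels, where it was equal on all arrays, in the comparison of the schedules. The plot of genes fixed in advance gives the per-array values.

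**Figure D1:**
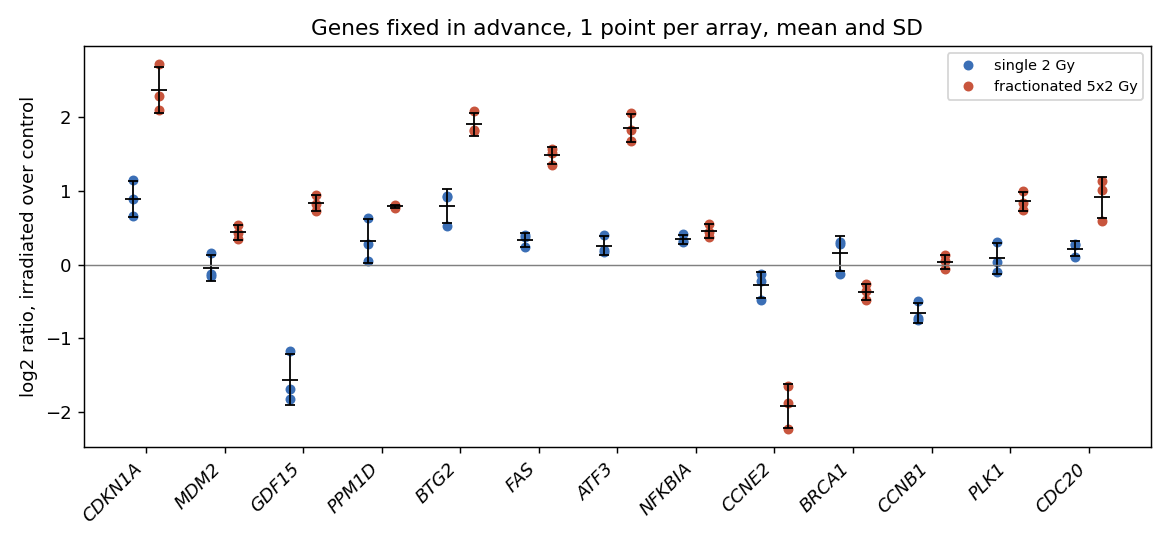
Log2 ratio of irradiated over control RNA on the vertical axis for genes fixed before the data were examined. Each point is an array, blue for the single 2 Gy dose and red for 5x2 Gy, and the bars give the mean and SD of 3 arrays. CDKN1A had mean log2 ratios of 0.90 and 2.37, GDF15 of -1.56 and 0.84, and CCNE2 of -0.28 and -1.92, after the single and the fractionated doses.

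The first comparison asked which genes responded to a single 2 Gy dose. Of 38 tested histone genes 1 rose and 22 fell (adjusted p = 1.73e-06 in limma's camera list test, adjusted p = 0.571 with an estimated correlation). Of 54 tested G2 and mitosis genes 0 rose and 27 fell (adjusted p = 2.72e-04 in limma's camera list test, adjusted p = 0.571 with an estimated correlation), and of 30 tested immediate early genes 12 rose and 0 fell (adjusted p = 0.00146 in limma's camera list test, adjusted p = 0.466 with an estimated correlation). H3C13, a histone H3 gene, had a log2 ratio of -1.61 ± 0.0984 (adjusted p = 9.74e-07), and HMMR, a mitotic spindle protein gene, -0.94 ± 0.101 (adjusted p = 5.34e-05). JUND, a subunit of the AP-1 transcription factor, rose 4.45-fold, with a log2 ratio of 2.16 ± 0.161 (adjusted p = 4.19e-06). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 and is a p53 target, rose 1.86-fold (log2 0.90 ± 0.132, adjusted p = 4.11e-04). GDF15, a stress-induced cytokine, fell, with a log2 ratio of -1.56 ± 0.125 (adjusted p = 6.78e-06).

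In limma's moderated test, 5237 of 16513 genes passed an adjusted p of 0.05, 2274 higher and 2963 lower in irradiated cells. Of these, 420 changed at least 2-fold, 271 up and 149 down. With median centring in place of loess the split was 2553 higher and 2434 lower, or 51.2% higher against 43.4%. Without replicate 1 the count was 3395 and without replicate 2 it was 3437.

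The highest ratio belonged to BSG, a membrane glycoprotein, which rose 6.56-fold (log2 2.71 ± 0.119, adjusted p = 5.96e-08). PDLIM7 had a log2 ratio of 2.33 (median 1.11 on its other probes) and ZYX, a focal adhesion gene, 2.24. HMGA1, an architectural chromatin protein, reached 2.26, the splicing factor gene SF3B4 2.13 and the linker histone gene H1-10 2.01. NUCB1 stood at 1.99 and ABHD14B at 1.99. ND2, a mitochondrially encoded subunit of complex I, was saturated in the irradiated channel and was at least 3.84-fold higher. The lowest ratios were -4.76 for AQP6, an aquaporin gene, -4.12 for CCDC88C, -3.88 for LCE3C, a cornified envelope gene, and -3.21 for NID2, a basement membrane gene. Both other probes of CCDC88C went the opposite way, with a median log2 ratio of 0.517, and where only probes above background in both channels on all arrays were kept the gene had 0.62. AQP6, CCDC88C and NID2 were well above background in the irradiated channel on 1 of 3 arrays, SLC22A7 on 2. SLC22A7 had -2.94, while its other probe read -0.32. CRACR2B had -2.53. MS4A6A, CACNG8 and LCE3A were not well above background in the irradiated channel and were at least 8.85-fold, 5.15-fold and 3.69-fold lower. The dyes were not swapped, so a dye effect of single probes is not separated from a response in these ratios and bounds. Of 80 genes at least 2-fold lower after both schedules, 14 had another probe, which showed 0.161 of the change. Of 179 at least 2-fold higher, 42 had one, which showed 0.542.

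Of the 24 gene lists tested, 7 were called, 5 up and 2 down, with the preset correlation, and without replicate 3 the number was 4. Among histone genes 1 rose and 24 fell adjusted over the list alone, with a median log2 ratio of -0.517. H3C8 and H4C2 fell to -1.61 and -1.63. Histone genes are near-identical copies, so a probe can read more than its own gene. Among G2 and mitosis genes 0 rose and 28 fell adjusted over the list alone, with a median of -0.307. CCNB1, the cyclin of mitotic entry, had a log2 ratio of -0.66 and the kinesin gene KIF20A -0.68, while PLK1 at 0.09 and CDC20 at 0.22 did not pass (adjusted p = 0.584 and 0.175).

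Among immediate early genes 12 rose and 0 fell adjusted over the list alone, with a median of 0.241, which was 0.156 without replicate 3 and 0.115 with the mean of all probes of a gene. FOSL1 and FOSB, further AP-1 subunits, rose 3.47-fold and 2.02-fold, and CCN1, a matricellular protein gene, to 0.76. ATF3 had 0.26 (adjusted p = 0.0869), and its other probes went the opposite way. In the NF-kB and cytokine list 8 of 20 tested members rose and 1 fell, or 9 and 1 adjusted over the list alone, with a median of 0.239 (adjusted p = 0.0155 in the list test and adjusted p = 0.466 with an estimated correlation), and it was not called with spots of flag 3 left out (adjusted p = 0.0633). The median of that list was 0.136 without replicate 3 and 0.132 with the mean of all probes. NFKB2 rose to 1.64, TNIP1 to 0.96, LIF to 0.60 and NFKBIA, the inhibitor of NF-kB, to 0.35, which did not pass without replicate 1 or 2 (adjusted p = 0.0538 and 0.0969). For p53 targets 13 of 41 tested members rose and 2 fell, or 14 and 2 adjusted over the list alone, with a median of 0.139 (adjusted p = 0.0155 in the list test and adjusted p = 0.571 with an estimated correlation). The p53 list was not called without replicate 3 (median 0.0916, adjusted p = 0.223), with only probes above background in both channels (adjusted p = 0.123) or in fry (adjusted p = 0.0945), and its median was 0.213 without replicate 1. PHLDA3 and BTG2 rose to 0.72 and 0.79, and FAS to 0.34, which did not pass without replicate 2 or 3 (adjusted p = 0.112 and 0.0624). MDM2, the ubiquitin ligase of p53, had -0.04 (adjusted p = 0.779) and the phosphatase gene PPM1D 0.32 (adjusted p = 0.0514).

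For ribosomal proteins 9 of 55 tested members rose and 0 fell, or 6 and 0 adjusted over the list alone, with a median of 0.112 (adjusted p = 0.00312 in the list test and adjusted p = 0.571 with an estimated correlation), and the median turned to -0.0841 with spots of flag 3 left out. Without replicate 3 the ribosomal median was 0.0426 and the list was not called (adjusted p = 0.205), nor was it with all arrays in fry (adjusted p = 0.102). The median was 0.196 without replicate 1, 0.175 without replicate 2, 0.412 with median centring, 0.274 with spot medians and 0.0662 with array weights. RPL38 reached 0.76, saturated on 2 of 3 arrays. Among mitochondrially encoded and nuclear long non-coding RNAs 8 of 20 tested members rose and 2 fell, or 9 and 3 adjusted over the list alone, with a median of 0.24 (adjusted p = 0.0452 in the list test and adjusted p = 0.571 with an estimated correlation), and the median turned to -0.0785 with spots of flag 3 left out. Without replicate 1 the median was 0.078 and without replicate 3 0.252, and neither was called (adjusted p = 0.153 and 0.102), while it was 0.402 with median centring. The call was also lost in the deposited table (adjusted p = 0.0673), without background subtraction (0.0682), without the filter on dim probes (0.0724), with probes above background in both channels (0.123), with the mean of all probes (0.0586), with array weights (0.0733), with slide as a random block (0.0628), with normexp on negative controls (0.0749) and in fry (0.0945). ND1 and ND5 rose to 1.52 and 1.71, and ND1 was saturated on 1 of 3 arrays in the irradiated channel.

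The remaining lists were not called, and the adjusted p is that of camera. Of 47 S phase and DNA replication genes 3 rose and 8 fell (3 and 8 adjusted over the list alone, adjusted p = 0.682). Of 34 genes of homologous recombination and the Fanconi anaemia pathway 1 rose and 5 fell (0 and 2 adjusted over the list alone, adjusted p = 0.381). Of 26 end joining and base excision repair genes 4 rose and 6 fell (4 and 7 adjusted over the list alone, adjusted p = 0.93). Of 30 apoptosis and death receptor genes 4 rose and 6 fell (4 and 7 adjusted over the list alone, adjusted p = 0.692). Of 34 interferon-stimulated genes 3 rose and 9 fell (3 and 9 adjusted over the list alone, adjusted p = 0.381). E2F1, a transcription factor of S phase entry, rose to 0.98, whereas CCNE2 had -0.28 and BRCA1 0.15, and neither passed (adjusted p = 0.108 and 0.317). BCL2L1, an anti-apoptotic gene, rose to 1.49. Of 35 ER stress and amino acid response genes 9 rose and 4 fell (9 and 5 adjusted over the list alone, adjusted p = 0.181). Of 28 NRF2 oxidative stress genes 4 rose and 6 fell (4 and 7 adjusted over the list alone, adjusted p = 0.692). Of 24 heat shock genes 2 rose and 3 fell (2 and 3 adjusted over the list alone, adjusted p = 0.692). Of 28 cholesterol synthesis genes 3 rose and 5 fell (3 and 5 adjusted over the list alone, adjusted p = 0.692). Of 32 hypoxia and glycolysis genes 5 rose and 3 fell (4 and 2 adjusted over the list alone, adjusted p = 0.216). SLC7A5, an amino acid transporter, rose to 1.46 while DDIT3 fell to -0.85, and EPHX1 rose to 1.52.

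The tissue and housekeeping lists were not called either. Of 21 Wnt targets and stem cell markers 4 rose and 4 fell (4 and 4 adjusted over the list alone, adjusted p = 0.55). Of 17 intestinal differentiation genes 1 rose and 4 fell (1 and 4 adjusted over the list alone, adjusted p = 0.397). Of 31 epithelial junction and keratin genes 6 rose and 5 fell (6 and 5 adjusted over the list alone, adjusted p = 0.397). Of 32 mesenchymal and matrix genes 5 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.149). Of 39 ribosome biogenesis genes and MYC targets, called the ribosome biogenesis list below, 9 rose and 4 fell (9 and 5 adjusted over the list alone, adjusted p = 0.216). Of 44 oxidative phosphorylation genes 3 rose and 9 fell (1 and 8 adjusted over the list alone, adjusted p = 0.692). Of 6 leukocyte markers 3 rose and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.216). The epithelial list had a median of -0.0094 and a mean of 0.0905, so that median and mean differed in sign. JUP, a junction protein gene, rose to 1.14, ITGA3 to 1.10 and the glycolytic gene PKM to 1.62. CD68, a lysosomal glycoprotein also used as a macrophage marker, rose to 1.04 (0.59 without replicate 3). Of the fibroblast markers only 1 of 12 was tested and of the endothelial markers 4 of 8, too few for a list test. The hypoxia list, with a median of 0.118, was called with median centring (median 0.281, adjusted p = 0.0411). The ribosome biogenesis list, with a median of 0.0693, was called with median centring (median 0.212, adjusted p = 0.00963) and with spots of flag 3 left out (0.175, adjusted p = 0.0436). Fry, which tests a list by itself and not against other genes, called the apoptosis list (adjusted p = 0.0329), the interferon list (0.0466), the ER stress list (0.0316), the intestinal list (0.0316), the matrix list (0.0316), the ribosome biogenesis list (0.0257) and the leukocyte list (0.0466) as well. Of the single genes given above as not passing, CDC20 passed with median centring (0.37, adjusted p = 0.0498). Others passed in more than 1 setting, among them PPM1D without replicate 1 (0.46, adjusted p = 0.0285), ATF3 with median centring (0.31, adjusted p = 0.0396) and CCNE2 with spots of flag 3 left out (-0.34, adjusted p = 0.0203).

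The second comparison asked which genes responded to 5 fractions of 2 Gy. Of 47 tested S phase and DNA replication genes 0 rose and 43 fell (adjusted p = 1.82e-15 in limma's camera list test, adjusted p = 0.2 with an estimated correlation). Of 41 tested p53 targets 30 rose and 0 fell (adjusted p = 2.22e-09 in limma's camera list test, adjusted p = 0.2 with an estimated correlation), and of 32 tested hypoxia and glycolysis genes 21 rose and 1 fell (adjusted p = 3.00e-08 in limma's camera list test, adjusted p = 0.2 with an estimated correlation). CCNE2, the cyclin of the G1 to S transition, fell to a log2 ratio of -1.92 ± 0.123 (adjusted p = 7.38e-07). CDKN1A rose 5.18-fold (log2 2.37 ± 0.132, adjusted p = 3.87e-07). P4HA1, a collagen prolyl hydroxylase gene, rose 5.25-fold (log2 2.39 ± 0.0986, adjusted p = 2.31e-08). The histone gene H2AC19 rose 9.65-fold, with a log2 ratio of 3.27 ± 0.13 (adjusted p = 2.29e-08).

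In limma's test 7563 of 16513 genes passed an adjusted p of 0.05, 3627 higher and 3936 lower. At least 2-fold changes were seen for 774 genes, 509 up and 265 down. With median centring in place of loess the split was 5113 higher and 2762 lower, or 64.9% higher against 48%, and the median log2 ratio over all genes moved from -0.0337 to 0.0721.

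BSG rose 8.12-fold (log2 3.02 ± 0.119, adjusted p = 2.19e-08) and H1-10 reached 2.94. H2AC7, a further H2A gene, had 2.69. CD68, above background in control cells on 2 of 3 arrays, had 2.62 and CDKN1C, a cyclin-dependent kinase inhibitor gene, 2.51. NDRG1, a gene induced by hypoxia, had 2.41. ND5, saturated on 2 of 3 arrays, had 2.38, and ND2, saturated in the irradiated channel, was at least 5.25-fold higher. The lowest ratios were -4.66 for AQP6, -4.17 for LCE3C, -4.09 for CCDC88C and -3.24 for SLC22A7. Both other probes of CCDC88C again went the opposite way (median 0.31, and 0.40 where only probes above background in both channels on all arrays were kept), and the other probe of SLC22A7 read -0.157. NID2 had -2.72, CACNG8 -2.71 and CRACR2B -2.48. PPP1R27 was 6.05-fold lower, with a log2 ratio of -0.127 on its other probe. MS4A6A was not well above background in the irradiated channel and was at least 11.1-fold lower. A dye effect of single probes is not separated from a response in these ratios and bounds either.

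With the preset correlation 12 of 24 lists were called, 10 up and 2 down. Among S phase and DNA replication genes 0 rose and 43 fell adjusted over the list alone, with a median of -0.835. MCM5 and MCM6, subunits of the replicative helicase, fell to -1.27 and -1.27, and its cofactor CDC45 to -1.55. For p53 targets 30 rose and 0 fell adjusted over the list alone, with a median of 0.542. BTG2 rose to 1.91, PHLDA3 to 1.69, the death receptor gene FAS to 1.49, GDF15 to 0.84, PPM1D to 0.79 and MDM2 to 0.44. In the hypoxia and glycolysis list 22 rose and 1 fell adjusted over the list alone, with a median of 0.697. ENO2, a glycolytic enzyme gene, rose to 1.58 and ANGPTL4 to 1.44. In the ER stress and amino acid list 22 of 35 tested members rose and 2 fell, or 23 and 3 adjusted over the list alone, with a median of 0.524 (adjusted p = 2.09e-06 in the list test and adjusted p = 0.2 with an estimated correlation). PPP1R15A rose to 2.03, SLC7A5 to 1.76, CEBPB to 1.28 and DDIT3 to 1.20.

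Among immediate early genes 19 of 30 tested members rose and 3 fell, or 19 and 4 adjusted over the list alone, with a median of 0.518 (adjusted p = 3.77e-05 in the list test and adjusted p = 0.2 with an estimated correlation). JUND rose to 2.30, ATF3 to 1.86 and NR4A2 to 1.19. Among G2 and mitosis genes 28 of 54 tested members rose and 5 fell, or 29 and 6 adjusted over the list alone, with a median of 0.342 (adjusted p = 8.30e-05 in the list test and adjusted p = 0.377 with an estimated correlation), and 0.559 with median centring. UBE2C, an enzyme gene of the anaphase-promoting complex pathway, rose to 1.29, CCNF to 0.97, CDC20 to 0.91 and PLK1 to 0.86. CCNB1 had 0.04 (adjusted p = 0.757), and its other probe read -0.765. In the list of homologous recombination and the Fanconi anaemia pathway 1 of 34 tested members rose and 22 fell, or 1 and 22 adjusted over the list alone, with a median of -0.406 (adjusted p = 8.30e-05 in the list test and adjusted p = 0.379 with an estimated correlation). FANCI fell to -1.05, NBN to -1.02 and BRCA1 to -0.36, which did not pass without replicate 1 or 2 (adjusted p = 0.0645 and 0.115). Among histone genes 24 of 38 tested members rose and 9 fell, or 24 and 9 adjusted over the list alone, with a median of 0.61 (adjusted p = 2.75e-04 in the list test and adjusted p = 0.379 with an estimated correlation). H2AC25 rose to 1.65 and H2BC11 to 1.73.

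Among mitochondrially encoded and nuclear long non-coding RNAs 13 of 20 tested members rose and 1 fell, or 13 and 1 adjusted over the list alone, with a median of 0.512 (adjusted p = 5.20e-04 in the list test and adjusted p = 0.364 with an estimated correlation), and with spots of flag 3 left out the median was 0.0365 and the list was not called (adjusted p = 0.532). With median centring it was 0.872. ND1 rose 3.48-fold, saturated on 2 of 3 arrays, and SNHG5, a snoRNA host gene, 1.79-fold. In the NF-kB and cytokine list 11 of 20 tested members rose and 2 fell, or 11 and 2 adjusted over the list alone, with a median of 0.288 (adjusted p = 0.0228 in the list test and adjusted p = 0.212 with an estimated correlation), and the call was lost with median centring (adjusted p = 0.0741) and with probes above background in both channels (0.0835). NFKB2 and TNIP1 rose to 1.96 and 1.87, NFKBIA rose to 0.46, and NFKB1 fell to -0.81. For ribosomal proteins 11 of 55 tested members rose and 1 fell, or 7 and 1 adjusted over the list alone, with a median of 0.119 (adjusted p = 0.0303 in the list test and adjusted p = 0.514 with an estimated correlation). That median turned to -0.385 with spots of flag 3 left out, and the list was not called without replicate 2 (adjusted p = 0.0582), in the deposited table (0.0587), with probes above background in both channels (0.0511), with the mean of all probes (0.0832) or in fry (0.0837). With median centring it was 0.524 and with spot medians 0.335. RPL38 rose to 0.63, while RPL8 and RPL7A were saturated in the irradiated channel and at least 1.79-fold and 1.45-fold higher. Among epithelial junction and keratin genes 12 of 31 tested members rose and 3 fell, or 12 and 3 adjusted over the list alone, with a median of 0.162 (adjusted p = 0.0312 in the list test and adjusted p = 0.379 with an estimated correlation), and with spots of flag 3 left out the median turned to -0.0458. Without replicate 2 the epithelial median was 0.0441 and the list was not called (adjusted p = 0.0858), nor was it with probes above background in both channels (0.051), with the mean of all probes (0.0673) or with normexp on negative controls (0.0505). The median was 0.404 with median centring, 0.0666 without the filter on dim probes and 0.0708 with spot medians. CLDN4, a tight junction gene, rose to 1.90, JUP to 1.63 and CLDN7 to 1.19.

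The other lists were not called after fractionation, with the adjusted p of camera. Of 26 end joining and base excision repair genes 3 rose and 12 fell (3 and 12 adjusted over the list alone, adjusted p = 0.0614). Of 30 apoptosis and death receptor genes 8 rose and 5 fell (7 and 5 adjusted over the list alone, adjusted p = 0.702). Of 34 interferon-stimulated genes 11 rose and 6 fell (11 and 6 adjusted over the list alone, adjusted p = 0.0909). Of 28 NRF2 oxidative stress genes 8 rose and 8 fell (9 and 8 adjusted over the list alone, adjusted p = 0.959). Of 24 heat shock genes 4 rose and 6 fell (4 and 6 adjusted over the list alone, adjusted p = 0.835). Of 28 cholesterol synthesis genes 8 rose and 12 fell (8 and 13 adjusted over the list alone, adjusted p = 0.74). OASL, IRF9, ISG15 and IRF7 of the interferon list rose to 1.32, 1.04, 1.20 and 1.09. NQO1, an NRF2-linked enzyme gene, fell to -1.33. HSPA1A was not well above background in control cells and was at least 1.81-fold higher. Of 21 Wnt targets and stem cell markers 4 rose and 7 fell (4 and 8 adjusted over the list alone, adjusted p = 0.306). Of 17 intestinal differentiation genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p = 0.835). Of 32 mesenchymal and matrix genes 11 rose and 5 fell (11 and 6 adjusted over the list alone, adjusted p = 0.0909). Of 39 ribosome biogenesis genes and MYC targets 8 rose and 17 fell (8 and 17 adjusted over the list alone, adjusted p = 0.173). Of 44 oxidative phosphorylation genes 6 rose and 13 fell (5 and 11 adjusted over the list alone, adjusted p = 0.372). Of 6 leukocyte markers 3 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.371). LAMB3, a laminin chain gene, rose to 1.96, and AXIN2, a Wnt target, fell to -0.95. Median and mean differed in sign in the apoptosis list (-0.00888 and 0.0291), the NRF2 list (-0.0948 and 0.0282) and the heat shock list (-0.0807 and 9.84e-04). The end joining and base excision repair list, with a median of -0.175, was called without the filter on dim probes (median -0.171, adjusted p = 0.0428), with only the fractionated arrays (-0.175, adjusted p = 0.0434), without single-dose replicate 1 (-0.175, adjusted p = 0.0418), without fractionated replicate 3 (-0.212, adjusted p = 0.0354) and with spot medians (-0.24, adjusted p = 0.0357). The interferon list, with a median of 0.0588, was called without the filter on dim probes (median 0.0812, adjusted p = 0.0401) and without fractionated replicate 3 (0.115, adjusted p = 0.0447). Fry, which tests a list by itself and not against other genes, called the end joining and base excision repair list (adjusted p = 0.00591), the apoptosis list (0.0207), the interferon list (0.00463), the matrix list (0.00173), the ribosome biogenesis list (0.00141) and the leukocyte list (0.0158) as well. CCNB1 passed as higher with median centring (0.37, adjusted p = 0.0197) and as lower with the mean of all probes of a gene (-0.36, adjusted p = 0.0114).

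The third comparison asked where the responses to the schedules differed, each array's ratio being taken against its own control channel. Relative to the single dose, of 47 tested S phase and DNA replication genes 0 were higher and 37 lower (adjusted p = 3.74e-23 in limma's camera list test, adjusted p = 0.142 with an estimated correlation). Of 38 tested histone genes 23 were higher and 0 lower (adjusted p = 2.41e-15 in limma's camera list test, adjusted p = 0.142 with an estimated correlation), and of 54 tested G2 and mitosis genes 33 were higher and 0 lower (adjusted p = 1.53e-15 in limma's camera list test, adjusted p = 0.142 with an estimated correlation). H2AC19 differed 15.9-fold, by 3.99 ± 0.184 on the log2 scale (adjusted p = 1.02e-06). GDF15 differed by 2.40 ± 0.177 (adjusted p = 1.68e-05), having fallen after the single dose and risen after fractionation. CDKN1A was 2.78-fold higher after fractionation (1.47 ± 0.187, adjusted p = 6.18e-04). CCNE2 was lower after fractionation, with a difference of -1.64 ± 0.174 (adjusted p = 2.75e-04).

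In limma's test 2400 of 16513 genes differed at an adjusted p of 0.05, 1320 higher and 1080 lower after fractionation, and 328 differed at least 2-fold, 223 up and 105 down. With median centring in place of loess the split was 2006 higher and 609 lower, or 76.7% higher against 55%. Slide 1 held the 3 single-dose arrays and fractionated replicate 1, and slide 2 held the other fractionated arrays. With slide as a fixed term 419 genes were called, 380 of them among the 2400, and within slide 1 alone 123, 103 of them shared. Of 101 named genes called, 44 were not called with slide as a term and 72 not within slide 1. Over the 2400 genes the median size of the difference was 0.678 with a median SE of 0.153, and 0.67 with 0.219 with slide as a term. At the median, calls thus ended with a larger error at a similar size, though the genes were chosen on the same arrays. For the 44 named genes not called with slide as a term the median size was 0.769, and 0.685 with the term. Leaving out single-dose replicate 1 or 2 or fractionated replicate 2 or 3 gave 1491, 1464, 1442 and 1204 genes, and spot medians gave 1493.

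Beside H2AC19, the genes highest after fractionation included H2AC7 (3.34), H2AC8 (2.49), H2BC9 (2.33) and the linker histone gene H1-2 (2.55). ALDOC, a glycolytic aldolase gene, differed by 2.61 ± 0.347, CDKN1C by 2.58 ± 0.146, ANGPTL4 by 2.34 ± 0.161 and NDRG1 by 2.27 ± 0.276. With slide as a fixed term these genes, H2AC19 apart, gave between 2.13 and 3.27 and remained called. Among the lowest were CDCA7 at -1.93 ± 0.157, HMGA2 at -1.73 ± 0.201 (median -0.338 on its other probes) and FADS1, a fatty acid desaturase gene, at -1.64 ± 0.186. ATF5 had -1.61, TYMS, the thymidylate synthase gene, -1.57, ADGRA3 -1.53 and KLHL42 -1.47. FPGS had -1.49 ± 0.409 and was not called with slide as a term (-1.40, adjusted p = 0.258) or when any 1 fractionated replicate was left out (adjusted p from 0.0651 to 0.104), while without single-dose replicate 3 it had -0.83. CYB5B was not well above background in the irradiated channel after fractionation and was at least 3.25-fold lower.

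With the preset correlation 11 of 24 lists differed, 7 higher and 4 lower after fractionation. The list medians with slide as a fixed term were equal to those within slide 1. Among S phase and DNA replication genes 0 were higher and 41 lower adjusted over the list alone, with a median difference of -0.678, and -0.677 with slide as a term. MCM10 differed by -1.25, MCM6 by -1.25 and E2F1 by -1.07. Among G2 and mitosis genes 39 were higher and 0 lower adjusted over the list alone, with a median difference of 0.633, and 0.459 with slide as a term. TPX2, a spindle assembly gene, differed by 1.35, CDC25C by 1.13 and TTK by 1.11. PLK1 differed by 0.78 and CDC20 by 0.70, while CCNB1 gave 0.70 on its main probe and -0.24 on the other. Among histone genes 24 were higher and 1 lower adjusted over the list alone, with a median difference of 0.788, and 0.784 with slide as a term. For p53 targets 13 of 41 tested members were higher and 1 lower, or 20 and 1 adjusted over the list alone, with a median difference of 0.442 (adjusted p = 2.29e-08 in the list test and adjusted p = 0.172 with an estimated correlation), and 0.418 with slide as a term. BBC3, a pro-apoptotic gene, differed by 1.53, GADD45A by 1.17, FAS by 1.14, BTG2 by 1.11 and MDM2 by 0.49 (adjusted p = 0.0452), while PPM1D gave 0.47 (adjusted p = 0.078).

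In the hypoxia and glycolysis list 16 of 32 tested members were higher and 1 lower, or 18 and 1 adjusted over the list alone, with a median difference of 0.552 (adjusted p = 7.56e-08 in the list test and adjusted p = 0.142 with an estimated correlation), and 0.576 with slide as a term. P4HA1 differed by 2.17. In the ER stress and amino acid list 16 of 35 tested members were higher and 2 lower, or 17 and 3 adjusted over the list alone, with a median difference of 0.457 (adjusted p = 2.08e-05 in the list test and adjusted p = 0.142 with an estimated correlation), and 0.367 with slide as a term. DDIT3, a stress transcription factor gene, differed by 2.06, HERPUD1 by 1.39 and DDIT4 by 1.36. In the homologous recombination and Fanconi list 0 of 34 tested members were higher and 10 lower, or 0 and 10 adjusted over the list alone, with a median difference of -0.298 (adjusted p = 1.44e-04 in the list test and adjusted p = 0.465 with an estimated correlation), and -0.385 with slide as a term. Its median was -0.164 with median centring, and it was not called in fry (adjusted p = 0.0833). NBN differed by -1.07, RBBP8 by -0.79, ATR by -0.52 and BRCA1 by -0.52. In the list of ribosome biogenesis genes and MYC targets 2 of 39 tested members were higher and 10 lower, or 2 and 13 adjusted over the list alone. Its median difference was -0.311 (adjusted p = 2.59e-04 in the list test and adjusted p = 0.142 with an estimated correlation). The median was -0.254 with slide as a term, -0.14 with median centring and -0.511 with spots of flag 3 left out. UTP20 differed by -1.05 and PAICS by -0.80. Among interferon-stimulated genes 9 of 34 tested members were higher and 0 lower, or 9 and 0 adjusted over the list alone, with a median difference of 0.152 (adjusted p = 0.00474 in the list test and adjusted p = 0.174 with an estimated correlation), and 0.172 with slide as a term, 0.233 with median centring. IRF7, ISG15, OASL and IRF9 differed by 1.45, 1.38, 1.24 and 1.01. In the end joining and base excision repair list 2 of 26 tested members were higher and 5 lower, or 2 and 8 adjusted over the list alone, with a median difference of -0.118 (adjusted p = 0.0241 in the list test and adjusted p = 0.403 with an estimated correlation), and -0.204 with slide as a term. That list was not called without single-dose replicate 2 or fractionated replicate 2 (adjusted p = 0.0609 and 0.0553), with median centring (median -0.0113, adjusted p = 0.0668) or with spots of flag 3 left out (adjusted p = 0.206), and its median was -0.222 without fractionated replicate 3. UNG, the uracil glycosylase gene, differed by -1.47 and PRKDC by -0.91. Among mitochondrially encoded and nuclear long non-coding RNAs 3 of 20 tested members were higher and 0 lower, or 3 and 0 adjusted over the list alone, with a median difference of 0.363 (adjusted p = 0.0396 in the list test and adjusted p = 0.465 with an estimated correlation), and 0.0625 with slide as a term, where the list was no longer called (adjusted p = 0.47). Without single-dose replicate 2 or fractionated replicate 3 its median was 0.173 and 0.163 and the call was lost (adjusted p = 0.173 and 0.165), as it was with spots of flag 3 left out (0.208), with normexp on negative controls (0.0553) and in fry (0.15). SNHG5 differed by 0.77 and TUG1 by 0.76, and the calls of TUG1, ATR, BRCA1 and MDM2 were lost when any 1 of single-dose replicates 1 and 2 and fractionated replicates 1, 2 and 3 was left out (adjusted p from 0.0563 to 0.15). CDC20 lost its call without single-dose replicate 2 or fractionated replicate 2 or 3 (adjusted p from 0.0588 to 0.0763).

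No difference was called for the other lists, with the adjusted p of camera. Of 30 immediate early genes 9 were higher and 2 lower (10 and 4 adjusted over the list alone, adjusted p = 0.0577). Of 21 Wnt targets and stem cell markers 2 were higher and 4 lower (2 and 4 adjusted over the list alone, adjusted p = 0.0862). Of 30 apoptosis and death receptor genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.433). Of 20 NF-kB and inflammatory cytokine genes 3 were higher and 1 lower (4 and 3 adjusted over the list alone, adjusted p = 0.715). Of 28 NRF2 oxidative stress genes 5 were higher and 2 lower (7 and 3 adjusted over the list alone, adjusted p = 0.967). Of 24 heat shock genes 4 were higher and 4 lower (5 and 4 adjusted over the list alone, adjusted p = 0.775). ATF3 differed by 1.60 and BTG1 by 1.19, TCF7 by -1.08, and NFKBIA gave 0.11 (adjusted p = 0.647). Of 28 cholesterol synthesis genes 4 were higher and 2 lower (4 and 4 adjusted over the list alone, adjusted p = 0.967). Of 17 intestinal differentiation genes 1 was higher and 0 lower (0 and 0 adjusted over the list alone, adjusted p = 0.433). Of 31 epithelial junction and keratin genes 4 were higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.0925). Of 32 mesenchymal and matrix genes 8 were higher and 3 lower (9 and 5 adjusted over the list alone, adjusted p = 0.463). Of 55 ribosomal protein genes 0 were higher and 1 lower (0 and 1 adjusted over the list alone, adjusted p = 0.765). Of 44 oxidative phosphorylation genes 1 was higher and 0 lower (0 and 0 adjusted over the list alone, adjusted p = 0.433). Of 6 leukocyte markers 1 was higher and 0 lower (1 and 1 adjusted over the list alone, adjusted p = 0.967). CLDN4 differed by 1.74, ESRP1 by 1.27, LAMB3 by 1.53, MSMO1 by 1.28 and CD68 by 1.58. Median and mean differed in sign for the NRF2 (-0.0621 and 0.0418), cholesterol (-0.0146 and 0.0155), mesenchymal (-0.0131 and 0.122) and leukocyte lists (-0.036 and 0.19). The immediate early list, with a median of 0.186, was called with median centring (median 0.322, adjusted p = 0.0222), without the filter on dim probes (0.186, adjusted p = 0.0176), with the mean of all probes (0.186, adjusted p = 0.0432), with array weights (0.225, adjusted p = 0.0485), with slide as a term (0.28, adjusted p = 0.0318), within slide 1 (0.28, adjusted p = 0.0371), without fractionated replicate 2 (0.294, adjusted p = 0.0323) and with spots of flag 3 left out (0.26, adjusted p = 0.0212). The Wnt list, with a median of -0.202, was called with slide as a term (median -0.218, adjusted p = 0.011), within slide 1 (-0.218, adjusted p = 0.0102), without single-dose replicate 1 (-0.175, adjusted p = 0.036) and without fractionated replicate 2 (-0.162, adjusted p = 0.0323). The epithelial list, with a median of 0.0891, was called with median centring (median 0.23, adjusted p = 0.039), without the filter on dim probes (0.0891, adjusted p = 0.0463) and without fractionated replicate 3 (0.13, adjusted p = 0.0423). Fry, which tests a list by itself and not against other genes, called the apoptosis list (adjusted p = 0.00533), the immediate early list (0.00533) and the matrix list (0.0457) as well. PPM1D passed in several settings, among them without single-dose replicate 3 (0.63, adjusted p = 0.015).

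**Figure D2:**
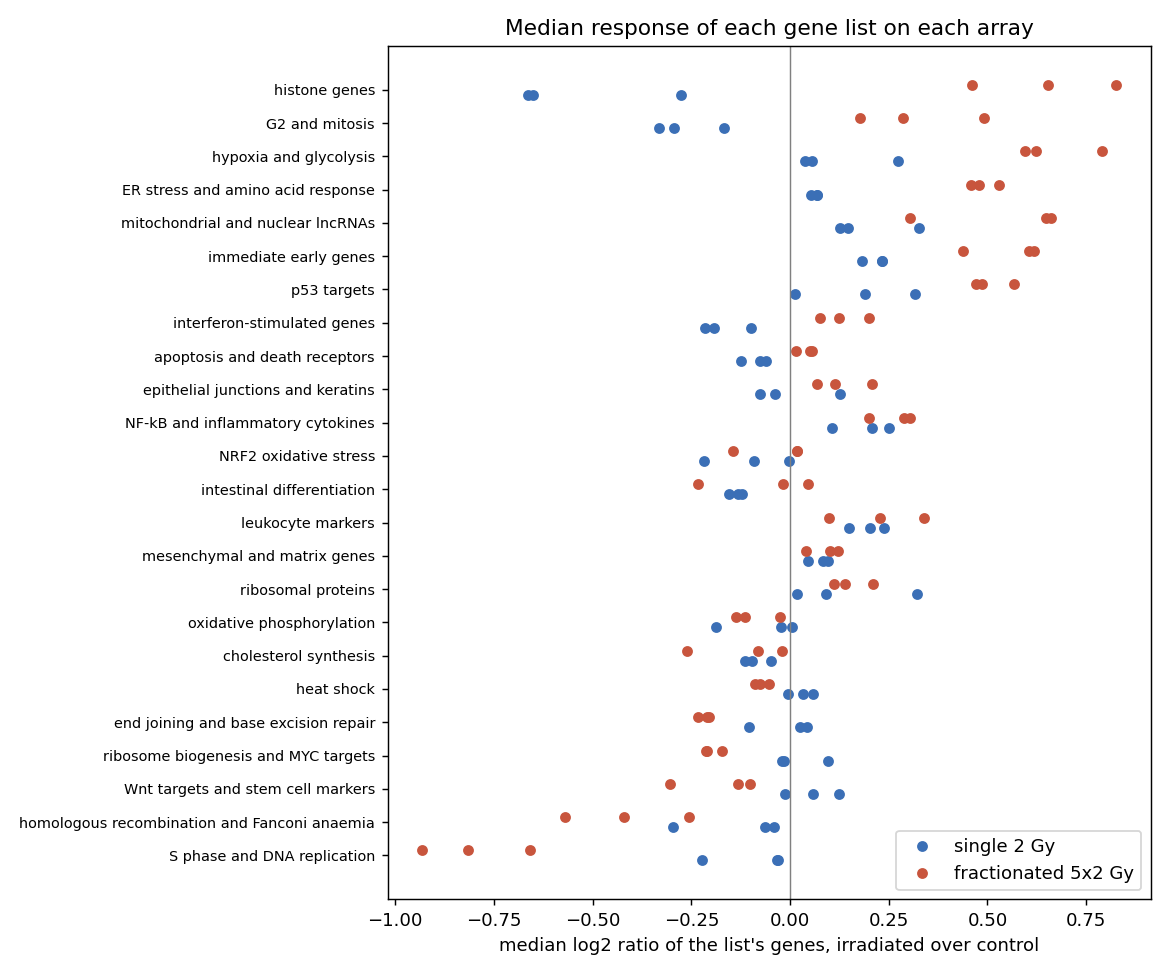
Median log2 ratio of irradiated over control RNA of each tested gene list on the horizontal axis, with a point per array, blue for the single 2 Gy dose and red for 5x2 Gy, and lists ordered by the difference between the schedules. The histone list has medians over genes of -0.517 after the single dose and 0.61 after fractionation, and the S phase list -0.0802 and -0.835.

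Across the 16513 genes, which are not independent replicates, the mean log2 ratios of both schedules correlated with Pearson's r = 0.634 and Spearman's rho = 0.573. Both schedules called 3190 genes in the same direction. Of these 1485 were higher and 1705 lower, against 499.5 and 706.3 for independent lists of those sizes, and 211 genes were called in opposite directions. The labels do not say whether arrays shared control extracts. The covariance of the ratios was 0.118 for arrays with the same replicate number and 0.124 for those with different numbers. A shared control or a dye effect would add to this overlap. Both tests also share each gene's pooled error, so the lists are not independent. The counts for independent lists are thus no test of a common response. At 2-fold or more, 179 genes were higher after both schedules and 80 lower, and 168 and 77 of these were not called between the schedules. Of the 2400 genes that differed, 1566 were not called after the single dose.

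**Figure D3:**
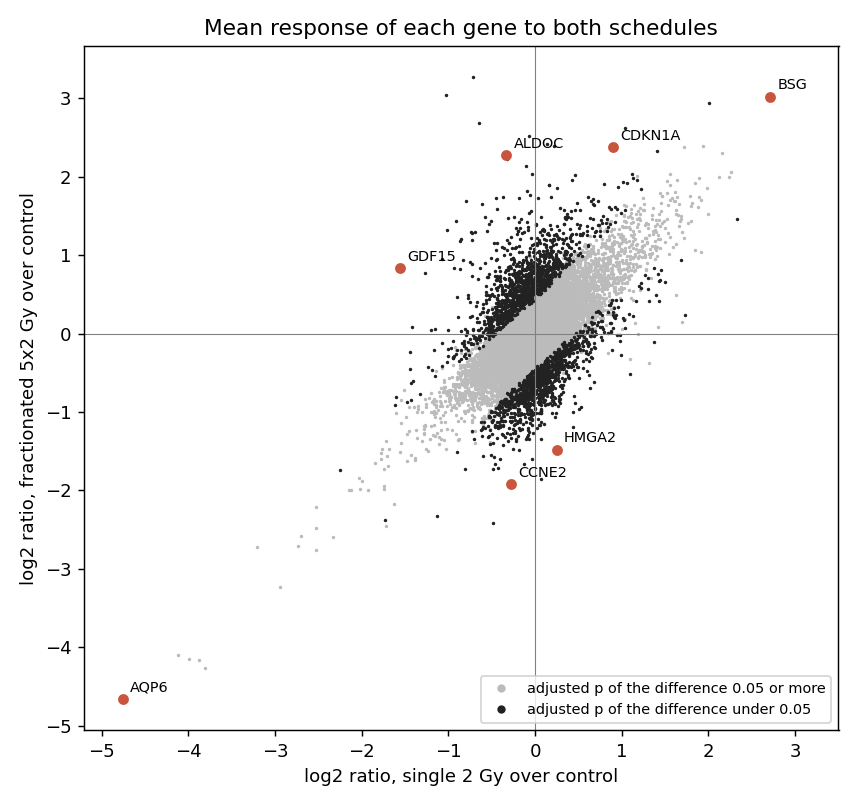
Mean log2 ratio of irradiated over control of each gene, single 2 Gy on the horizontal and 5x2 Gy on the vertical axis, with black points for the 2400 genes that differ between the schedules at an adjusted p of 0.05 and red points for named genes. AQP6 lies at -4.76 and -4.66 and BSG at 2.71 and 3.02, while GDF15 lies at -1.56 and 0.84.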

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

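The results listed here were picked because the response to fractionated doses differed from that to the single dose in a test of the difference itself, limma's contrast of the schedules for genes and camera for lists. The coverage rule for other probes, by which a comparison covering too few members of a set is void, was applied after its values had been seen, as was the rule that a single array excludes nothing. In the predictions as written, under 0.25 of a change on other probes meant a dye effect. At least 0.5, with a lower bound over 0.25, counted against one. By these limits alone, the falls after both schedules (0.161) would have been read as a dye effect, not a common response. The rises (0.542) and the differences between schedules (0.502) would have counted against a dye effect, and the slide test (0.874) against slides. The later rules left all of these open. The tests with slide as a term and the values of other probes at 2-fold or more were also chosen after the result had been seen. The remaining tests had predictions written beforehand. Ranges in brackets after a share of a change or a median difference are bootstrap bounds over genes from 2000 draws. They do not measure the spread between replicate arrays.

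In all, 2400 genes differed, and 11 lists did in the list test with the preset correlation. With an estimated correlation these 11 had an adjusted p = 0.142 to adjusted p = 0.465 and none was called. Medians above 0 were 0.788 for histone genes, 0.633 for G2 and mitosis, 0.552 for hypoxia and glycolysis, 0.457 for ER stress and amino acid response, 0.442 for p53 targets, 0.363 for mitochondrially encoded and nuclear long non-coding RNAs (0.0625, adjusted p = 0.47, with slide as a term) and 0.152 for interferon-stimulated genes. Medians below 0 were -0.678 for S phase and DNA replication and -0.311 for ribosome biogenesis and MYC targets. The others below 0 were -0.298 for homologous recombination and Fanconi anaemia and -0.118 for end joining and base excision repair.

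Named genes are given as the log2 difference, fractionated minus single, in the words of the lists they come from. These genes are picked members, and a list named here need not have been called between the schedules. The immediate early, apoptosis, NF-kB, NRF2, heat shock, cholesterol, Wnt, epithelial, matrix, ribosomal protein, oxidative phosphorylation and leukocyte lists were not called. Histone genes differed by 3.99 for H2AC19, 3.34 for H2AC7, 2.49 for H2AC8 and 2.26 for H2AC25. S phase genes differed by -1.07 for E2F1, -1.25 for MCM6 and -1.25 for MCM10. G2 and mitosis genes differed by 1.35 for TPX2, 1.13 for CDC25C, 1.11 for TTK and 0.989 for HJURP. p53 targets differed by 1.53 for BBC3 and 1.17 for GADD45A. Hypoxia and glycolysis genes differed by 2.61 for ALDOC, 2.34 for ANGPTL4, 2.27 for NDRG1 and 2.17 for P4HA1. ER stress genes differed by 2.06 for DDIT3, 1.39 for HERPUD1, 1.36 for DDIT4 and -1.61 for ATF5. Immediate early genes differed by 1.19 for BTG1, 0.923 for NR4A3 and 0.858 for NR4A2. Homologous recombination genes differed by -0.522 for ATR, -0.584 for FANCI, -0.794 for RBBP8 and -1.07 for NBN. End joining and base excision repair genes differed by 0.61 for XRCC4, -0.856 for XRCC6, -0.909 for PRKDC and -1.47 for UNG. Apoptosis genes differed by 0.8 for CASP9, 0.596 for DIABLO, 0.573 for HRK and -0.51 for CASP6. Interferon-stimulated genes differed by 1.45 for IRF7, 1.38 for ISG15, 1.24 for OASL and 1.01 for IRF9.

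NF-kB genes differed by 0.917 for TNIP1 and -0.861 for NFKB1. NRF2 genes differed by 0.962 for OSGIN1, 0.941 for FTL, 0.698 for HMOX1 and -1.05 for NQO1. Heat shock genes differed by 0.93 for HSPB8, -0.918 for HSPA8 and -1.12 for HSPH1. Cholesterol synthesis genes differed by 1.28 for MSMO1, 0.767 for HMGCS1, 0.706 for STARD4 and -0.868 for LSS. Wnt targets differed by 0.886 for KLF5, -0.959 for AXIN2 and -1.08 for TCF7. Epithelial genes differed by 1.74 for CLDN4, 1.27 for ESRP1, 0.786 for OCLN and -0.621 for LAD1. Matrix genes differed by 1.53 for LAMB3, 0.96 for PLAUR, 0.927 for ITGA5 and 0.81 for LAMA3. The ribosomal protein gene differed by -0.8 for RPL27A. Ribosome biogenesis genes and MYC targets differed by -0.707 for CTPS1, -0.723 for PUS7, -0.802 for PAICS and -1.05 for UTP20. The oxidative phosphorylation gene differed by 0.694 for COX7A2. Long non-coding RNAs differed by 0.77 for SNHG5, 0.765 for TUG1 and 0.57 for SNHG1. The leukocyte marker differed by 1.58 for CD68. Genes named by size or in advance differed by 2.58 for CDKN1C, 2.55 for H1-2, 2.4 for GDF15, 2.33 for H2BC9, 1.6 for ATF3, 1.47 for CDKN1A, 1.14 for FAS, 1.11 for BTG2, 0.776 for PLK1, 0.697 for CDC20, 0.697 for CCNB1, 0.486 for MDM2, -0.518 for BRCA1, -1.47 for KLHL42, -1.49 for FPGS, -1.53 for ADGRA3, -1.57 for TYMS, -1.64 for FADS1, -1.64 for CCNE2, -1.73 for HMGA2 and -1.93 for CDCA7.

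With slide as a term, 44 of the 101 named genes were not called (adjusted p from 0.0518 to 0.516), namely ATR, AXIN2, BIRC3, BRCA1, CASP6, CASP9, CCNB1, CD68, CDC20, COX7A2, CTPS1, DIABLO, FANCI, FPGS, FTL, HMGCS1, HMOX1, HRK, HSPA8, HSPB8, IL11, ITGA5, KLF5, LAD1, MDM2, NQO1, NR4A2, NR4A3, OCLN, OSGIN1, PLAUR, PLK1, PUS7, RBBP8, RPL27A, SNHG1, SNHG5, STARD4, TFF3, TNIP1, TUG1, UTP20, XRCC4 and XRCC6. When any 1 array was left out, calls were lost in at least 1 such fit (adjusted p from 0.0509 to 0.151) for ATR, BIRC3, BRCA1, CASP6, CDC20, COX7A2, CTPS1, DIABLO, FANCI, FPGS, FTL, HMOX1, HRK, IL11, LAD1, MDM2, SNHG1, STARD4, TFF3, TUG1 and XRCC4.

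Some fitted differences rest on a channel that was not well above background on any array of a schedule, so that only a bound holds. CYB5B (fitted -1.93) was at least 3.25-fold lower after fractionation and MYB (fitted -0.892) at least 1.63-fold lower, while TFF3 (fitted 0.458) was at least 1.05-fold higher. HSPA1A (fitted 1.25), BIRC3 (fitted 0.61) and IL11 (fitted 0.484) were not well above background in either channel after the single dose, and no size of their difference can be given.

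LSS, TFF3 and CCNB1 had other probes that went the opposite way, with median differences of 0.0396, -0.0819 and -0.24.

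For the genes that differed between the schedules, a difference of slides or a dye effect of single probes was weighed against one of schedules: among 1783 genes called between the single-dose arrays and the fractionated arrays of slide 2, the fractionated array on slide 1 showed 0.874 of their median difference (0.854 to 0.891), with the same sign for 98%, but this is a single array and the slide stays open. Both differences subtract the same single-dose arrays, which by itself makes them alike. With slide as a term 419 genes were called, while the median size over the 2400 genes was 0.67 against 0.678 with a median SE of 0.219 against 0.153. All 2400 kept their sign. This estimate rests on the same single array, which was also among the arrays by which the 2400 genes were chosen. Kept signs and sizes are thus partly built in. A dye effect equal on all arrays cancels in this comparison, and against one that varied between arrays other probes showed 0.502 of the difference (0.432 to 0.569) with the same sign for 80.9%, and 0.551 (0.428 to 0.66) with 89.1% for genes at 2-fold or more, but only 656 of 2400 genes had one, which leaves the rest open. Of the 10 splits of the 6 arrays into 3 and 3, 1 called as many genes, the real one with 2400 against a highest other of 0. These 10 splits are too few for a share under 0.05. Every other split mixes the schedules, so a difference between them enters the error. The lack of gene calls there is thus partly built in. For lists 2 of the 10 splits called as many, the real one 11 and the highest other 12. That split set single-dose replicates 1 and 2 and fractionated replicate 1, all on slide 1, against the rest, among them single-dose replicate 3, also on slide 1. The splits other than the real one called between 2 and 12 lists, each with 0 genes. A list call at the preset correlation thus does not by itself mark the schedules. With slide as a term 10 of the 11 lists kept their call. A difference in time in culture, with the harvest of the fractionated controls not given, stays open as well and was not tested.

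Genes at least 2-fold changed after both schedules were weighed as a dye effect of single probes against a response common to the schedules. Of the 80 genes lower after both, 14 had another probe, and these showed 0.161 of the change (-0.0889 to 0.34), with the same sign in 10. Of the 179 higher after both, 42 had another probe, which showed 0.542 (0.306 to 0.742), with the same sign in 34. Too few genes of either set had another probe and no array had the dyes swapped, so a dye effect and a response cannot be told apart.

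The 3 arrays of a schedule have only 4 sign patterns, too few for a share under 0.05. The real pattern called 5237 genes after the single dose and 7563 after fractionation, each 1 of 4 patterns with as many and against a highest other of 0. Any other pattern reverses 1 array against the rest. A ratio common to the 3 arrays, a dye effect included, then enters the error, so that the lack of gene calls is partly built in. For lists the real patterns called 7 after the single dose and 12 after fractionation, with 2 and 1 of 4 patterns giving as many and a highest other of 7 and 9.

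The higher p53 target genes after fractionation were weighed against members shared with the stress response driven by the transcription factor ATF4. The 8 such members taken out were GDF15, SESN2, TNFRSF10B, TNFRSF10A, BBC3, GADD45A, PMAIP1 and CDKN1A, with a median difference of 0.995. Without them the 33 remaining targets still had a median difference of 0.362 (0.275 to 0.46). Of these 33, 8 were higher and 1 lower at an adjusted p of 0.05 in limma's test. The test argues against these 8 members as the whole source of the shift. Whether remaining members also respond to that stress was not tested. Residual p53 after an incomplete knock-down may contribute, which was not tested, and the slide stays open as for the other lists.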

How the results depend on the processing

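The settings on slide as a fixed term, slide 1 alone, spot medians, flag 3 and normexp on negative controls were chosen after the data were seen. The number of genes called stayed within 1.5 times the reported one in the other settings except those named here, and the cause of each change was not tested unless fewer arrays or fewer genes account for it. Between the schedules 419 genes were called with slide as a fixed term, 123 within slide 1 and 1493 with spot medians. Leaving out 1 array gave 3395 to 5027 genes after the single dose, 5577 to 8209 after fractionation and 1204 to 2897 between the schedules. Lists numbered 4 to 7, 10 to 14 and 9 to 12. With an estimated correlation 0, 0 and 0 lists were called, against adjusted p from 0.142, and fry called 11 lists after the single dose. Genes at least 2-fold changed numbered 734, 1417 and 655 with normexp on negative controls, against 420, 774 and 328, and between the schedules 213 without background subtraction, 210 in the deposited table and 123 within slide 1. The correlation of the responses ran from 0.576 to 0.643. The replicate numbers showed no sign of pairing, as deviations of same-numbered arrays from their group mean correlated at -0.196, -0.083 and -0.0724. With 3 arrays per group such deviations are tied to each other, so pairing is not excluded. The replicate block gave 1837 genes between the schedules as a fixed term and 5232 and 7560 genes against control as a random block. Array weights ran from 0.497 for single-dose replicate 3 to 1.44. Signal over background limits the dim genes, whose folds were understated on simulated data.

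Of the list results called, counted once per setting, 626 kept their direction and call over all settings, 71 lost the call and 4 turned, while 41 list results not called gained a call. Of the named gene results called, 6415 kept both, 358 lost the call and 6 turned, and 27 not called gained one. The turned values are list medians, or the log2 value of a gene. Without background subtraction, these signs turned: epithelial 0.00492 after the single dose, and apoptosis 1.98e-04 after fractionation, and ribosomal protein 0.0048 between the schedules. With median centring in place of loess, these signs turned: cholesterol 0.0155, epithelial 0.0919, oxidative phosphorylation 0.151, MDM2 0.009544 after the single dose, and apoptosis 0.149, NRF2 0.217, heat shock 0.109, cholesterol 0.176, ribosome biogenesis 0.139, oxidative phosphorylation 0.244 after fractionation, and NRF2 0.0882, heat shock 0.0713, cholesterol 0.14, matrix 0.0597, ribosomal protein 0.0856, oxidative phosphorylation 0.096 between the schedules. With no filter on dim probes, these signs turned: intestinal 8.56e-04 after the single dose, and intestinal 0.0582 after fractionation, and cholesterol 0.0167, matrix 0.0117, leukocyte 0.0654 between the schedules. With probes well above background in both channels on all arrays, these signs turned: CCDC88C 0.6237 after the single dose, and intestinal 0.0879, CCDC88C 0.4024 after fractionation. With mean of all probes of a gene, these signs turned: FANCA -0.03976, OGG1 0.06949, ATF3 -0.05442, MDM2 0.05433 after the single dose, and CCNB1 -0.3615 after fractionation, and ribosomal protein 0.00752, leukocyte 0.0226 between the schedules. With array weights, these signs turned: apoptosis 0.00917 after fractionation, and matrix 0.0161, ribosomal protein 0.0351 between the schedules. With slide as a fixed term and likewise within slide 1, these signs turned: cholesterol 0.0153, intestinal -0.0169 between the schedules. With spots of flag 3 left out, these signs turned: ER stress -0.0272, heat shock -0.0105, ribosomal protein -0.0841, mitochondrial and long non-coding RNA -0.0785, HSPA8 -0.2561, PPM1D -0.00762 after the single dose, and epithelial -0.0458, ribosomal protein -0.385 after fractionation, and heat shock 0.0176, cholesterol 0.0183, epithelial -0.0203, oxidative phosphorylation 0.00334 between the schedules. With spot median in place of mean, these signs turned: end joining 0.00128, epithelial 0.0359, HSPB1 0.2618 after the single dose, and CCNB1 -0.003377 after fractionation, and matrix 0.0245, ribosomal protein 0.0593 between the schedules. Ranges over the fits without 1 array were, for results that turned in any, heat shock after the single dose -0.0215 to 0.0339, epithelial after the single dose -0.056 to 0.057, oxidative phosphorylation between the schedules -0.156 to 0.0377, matrix between the schedules -0.0334 to 0.0522, ribosome biogenesis after the single dose -0.0109 to 0.0693, ribosomal protein between the schedules -0.0814 to 0.0775, apoptosis after fractionation -0.0366 to 0.0397, intestinal after fractionation -0.182 to 0.00425, leukocyte between the schedules -0.0865 to 0.00926, heat shock between the schedules -0.109 to 0.0463, cholesterol after fractionation -0.15 to 0.0124, cholesterol between the schedules -0.0685 to 0.0902, MDM2 after the single dose -0.144 to 0.01306, PLK1 after the single dose -0.02936 to 0.1793, CCNB1 after fractionation -0.003015 to 0.09242.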

Other observations

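Classes of histone genes, metallothioneins and glycolytic enzymes, 7 families in all, were looked at after their values had been seen. Of 8 H2A genes tested 5 fell after the single dose and 7 rose after fractionation, with median log2 ratios of -0.591 and 1.67, and of 9 H2B genes 7 fell and 9 rose, with medians of -0.537 and 1.29. Of 10 H4 genes 0 were called between the schedules in limma's test at an adjusted p of 0.05 (4 at an unadjusted p of 0.05), with a median difference of 0.0716. Of them 5 fell after the single dose, and 2 rose and 5 fell after fractionation. H3 genes had 6 of 8 higher after fractionation than after the single dose, with a median difference of 0.74, while after fractionation 3 rose and 4 fell against control. H1 genes, of which 3 were tested, had medians of -0.202 and 1.26. After the single dose the 3 ran from -0.324 to 1.31. That median was 0.559 with spots of flag 3 left out, where members can drop out, so the turn need not be a change of any gene. The signs of the H2A, H2B, H3 and H4 medians stayed the same with median centring, Aquantile, the deposited table and spots of flag 3 left out. Copies of histone genes are near-identical, so a probe's gene is uncertain. Whether the probes read polyadenylated copies was not tested.

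Metallothioneins are proteins that bind zinc and other metals. Of 12 genes tested, 10 fell after fractionation, with no test of the family as a set. The median log2 ratio of all 12 was -0.591, a value that stayed negative with median centring (-0.501), in the deposited table (-0.579) and with spots of flag 3 left out (-0.582). MT1M fell to -2.33, lower on 3 of 3 arrays (adjusted p = 9.04e-07). Copies of this family are also near-identical. After the single dose 5 fell and MT2A rose (0.51, adjusted p = 0.00514). Between the schedules 3 of 12 were lower after fractionation, among them MT1M at -1.20 (adjusted p = 0.00422). Of 16 glycolytic enzyme genes 5 were higher after fractionation than after the single dose and 1 lower, with a median difference of 0.208 that turned to -0.119 with spots of flag 3 left out. ALDOC, ALDOA and ENO2 were higher, by 2.61, 1.18 and 1.06, while PFKM differed by -0.735.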
